A study of Drosophila melanogaster with 24 samples.

How the data were processed

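The series holds 24 arrays of adult fly brain neurons sorted by hand for GFP. Large PDF neurons were sampled at ZT0 and ZT12 (3 arrays each) and at ZT6 and ZT18 (2 arrays each). Small PDF neurons (2 arrays per time), ELAV neurons (3 arrays per time) and large PDF neurons of per01 flies (2 arrays per time) were sampled at ZT0 and ZT12. ELAV neurons are general neurons and serve as the reference for PDF neurons. ZT is zeitgeber time in hours of the 12 h light and 12 h dark cycle, with lights on at ZT0 by convention. Per the labels' protocols, about 50 brains were dissected for each sample, and biotinylated cRNA was made by 2 rounds of T7 amplification from sub-nanogram amounts of total RNA.

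The unit used is the deposited log2 GCRMA value of each probe set, made with GCRMA in R 2.6 per the submitters' processing notes. GCRMA corrects background with probe sequence, equalizes the distributions of arrays and summarizes the probes of a probe set. Which arrays were normalized together is not given in the sources used here. The deposited table has 18952 probe sets. Removing 183 control probe sets and keeping probe sets with a log2 value of at least 5 on at least 2 arrays left 8318 probe sets, of which 7217 carried exactly 1 gene symbol, for 6663 genes. In the annotation, 13647 probe sets carried 1 symbol, 402 carried several and 4720 carried none.

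Differences were estimated with limma's moderated test on the log2 values, with a mean for each of the 10 groups of cell kind, genotype and time. Variances were moderated without a trend (14 residual degrees of freedom, 3.62 prior degrees of freedom). P values were adjusted within each contrast by Benjamini and Hochberg, and a probe set was called at an adjusted p below 0.05. Contrasts between cell kinds or genotypes weight ZT0 and ZT12 equally, so the ZT6 and ZT18 arrays enter only the variance there. Time contrasts are ZT12 minus ZT0 within a kind. Interactions are differences between time contrasts. The time course of large PDF neurons was tested with limma's F test over its 4 times. The word rose, fell, higher or lower is used of genes that were called, and values are given for genes that were not called. A difference is given with its standard error. All p values for genes are adjusted, and the 24 arrays are few, so precision is limited by spread between replicate arrays. Per the labels the replicates are biological, and the p values measure spread between these samples of sorted cells.

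Where every array of the lower side lies under log2 5, values are mostly background, and the fold is given as at least the one found with values under 5 raised to 5. This bound is left out where leaving out 1 array moves it by more than 1.5-fold, and other differences are given in log2 only. Log2 differences that reach under 5 include background. Named genes follow a fixed rule. In each comparison these are 8 clock genes (per, tim, Clk, cyc, vri, Pdp1, cwo, cry) and Pdf, then the 8 largest rises and 8 largest falls with a named gene and the 2 largest each way with only a CG or CR number, then up to 4 called members of each gene list. A gene stands for its probe set with the highest mean over the 24 arrays. The yolk protein genes were added for the genotype comparison, where the flies differ in sex.

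The 27 gene lists were written before the data were examined. Each was tested with camera from limma at a preset correlation of 0.01 and again with a correlation estimated from the data, and with fry as an alternative. Counts of called members are given with counts from adjusting p over the list's members alone. While results were being read, matching through older gene names that stand for several genes was found to place a wrong gene in the ribosomal list. Such matches were removed and every result was computed again, which took 1 member from the ribosomal list and 1 from the chaperone list.

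The per01 arrays have their own value distribution (see the report), so the genotype comparison was also computed after all arrays were quantile normalized to a common distribution. That version is called requantiled. Other alternatives were no filter, a stricter filter at log2 7, a floor at log2 5, median centring, fitting only the groups in a contrast, a variance trend with robust moderation, array weights, a 2-fold threshold, 1 probe set per gene, the replicate number as a block, a 24-hour cosine regression for the time course and leaving out each array in turn. Leaving out all per01 arrays and using 2 wild-type arrays per time point were chosen after results were seen. An alternative was counted as different when it ended a call, turned the sign of a called difference or moved a count by more than 1.5-fold. A gene not called in either version was counted as the same whatever its sign.

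A self-test added known differences to 200 genes in simulated data with the same design and, for each probe set, 1 variance for all groups. In the data the spread was unequal, with a median residual standard deviation of 0.619 in large PDF, 0.508 in small PDF, 0.5 in ELAV and 0.401 in per01 neurons. The shares found therefore hold for equal spread and may be too favourable for large PDF neurons. In the time contrast of large PDF neurons 52% of 4-fold and 84% of 8-fold differences were found, with 6.3% false calls. In small PDF neurons these shares were 32% and 62%. Software was R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.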

Results

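PDF neurons are the brain's PDF-releasing clock neurons, and the large and small kinds were compared here with general neurons (ELAV), with each other, between ZT12 and ZT0, and with large PDF neurons of per01 flies. Medians of the deposited log2 values were 3.14 to 3.44 on the 20 wild-type arrays and 2.57 to 2.6 on the 4 per01 arrays. Of all probe sets, 32.9 to 36.6% reached log2 5 on wild-type arrays and 28.6 to 29.9% on per01 arrays. Correlations between replicate arrays ran from 0.878 (large PDF, ZT0) to 0.959 (per01, ZT12). Pdf was at 15.5 to 16 on large PDF arrays, at 15.8 to 15.9 on small PDF arrays and at 2.76 to 5.34 on ELAV arrays. The highest value of any probe set was 15.57 to 15.99 on large PDF arrays, so Pdf lay at the top of the range. Differences in Pdf between groups of PDF neurons may therefore be hidden, and its difference from ELAV may be understated. Gad1, which makes GABA, was at 9.5 on ZT18 replicate 2 of large PDF and at 7.1 on ZT0 replicate 1 of small PDF, and at most at 2.99 on the other PDF arrays of wild type. The glutamine synthetase gene Gs2 was at 9.53 on ZT0 replicate 2 of large PDF.

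**Figure D1:**
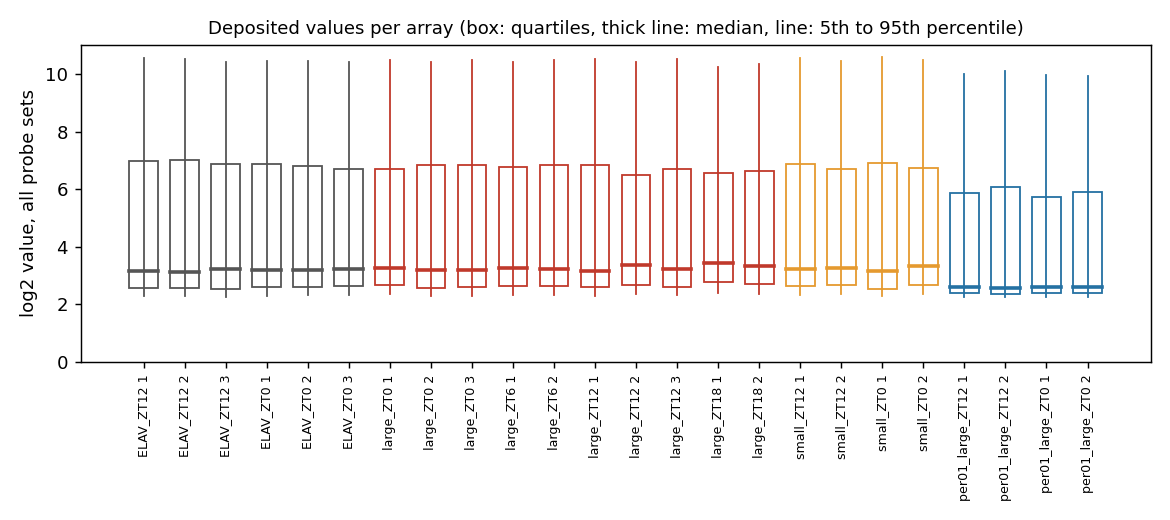
Deposited log2 values of all probe sets on the 24 arrays. Boxes give quartiles, thick lines medians and thin lines the 5th to 95th percentile.

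Large PDF neurons carried their own peptide, most core clock transcripts (not cyc, and Pdp1 only slightly) and the light receptor gene cry far above general neurons. Of 15 transmitter synthesis and transport genes 10 were lower in them, and of 22 neuropeptide genes 14. Ribosomal protein genes (12 of 30 higher) and respiratory chain genes (21 of 61 lower) were called by camera at its preset correlation only. Of 8318 probe sets 2030 were called, 991 higher and 1039 lower (1674 genes), and 1525 of these differed at least 2-fold. Among the largest rises were the neuropeptide gene Pdf (12.27 ± 0.30, adjusted p = 4.24e-15), CG17777 (7.87), cry (7.22 ± 0.47, adjusted p = 3.68e-09) and CG14292 (6.07 ± 0.22, at least 10.3-fold). Others were the cuticle protein genes Cpr60D (7.03 ± 0.35, at least 25.5-fold) and Cpr50Cb (6.17 ± 0.65, at least 12.2-fold), the prolyl isomerase gene Fkbp14 (7.03 ± 0.64) and the tetraspanin gene Tsp42Eo (6.30 ± 0.78, at least 18.2-fold). The bHLH factor gene Fer2 (5.42 ± 0.36) and the nuclear receptor gene Hr51 (5.01 ± 0.64) were also higher.

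Among the 8 measured core clock genes 7 were higher and 0 lower (camera adjusted p = 1.06e-08). These were vri (5.99 ± 0.40), tim (5.68 ± 0.31), Clk (5.07 ± 0.44, at least 7.05-fold, adjusted p = 1.11e-07), cry (7.22 ± 0.47), cwo (3.21 ± 0.26), per (3.19 ± 0.37) and Pdp1 (0.87 ± 0.29, adjusted p = 0.0322), while cyc stood at -0.27 (adjusted p = 0.497). Pdp1 lost its call in 7 of 12 fits without 1 array (adjusted p up to 0.0845, without ELAV ZT12 replicate 3). Of 11 genes known to cycle in whole heads 8 were higher and 0 lower (camera adjusted p = 4.96e-08). Of the 9 clock kinase and degradation genes 2 were higher, among them the ubiquitin ligase gene ctrip (1.64 ± 0.25), and 0 lower (camera adjusted p = 0.415). The translation activator gene of per, tyf (2.33 ± 0.36), was higher too.

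Neuropeptide genes fell, with 14 of 22 lower and 2 higher (16 and 2 adjusted over the list alone, camera adjusted p = 6.62e-07). The largest falls were ITP (-10.43 ± 0.90), FMRFa (-10.11 ± 0.43, at least 258-fold), Mip (-9.56 ± 0.51), Ms (-9.04 ± 0.61), sNPF (-8.77 ± 0.75) and CCHa2 (-8.68 ± 0.40). Transmitter synthesis and transport genes fell in the same way, with 10 of 15 lower and 0 higher (10 and 1 adjusted over the list alone, camera adjusted p = 1.54e-07). They include the vesicular monoamine transporter gene Vmat (-11.78 ± 0.36, at least 827-fold, adjusted p = 1.34e-13), Gad1 (-11 ± 0.77, at least 461-fold), the choline transporter gene ChT (-6.78 ± 0.83) and the tyrosine hydroxylase gene ple (-6.02 ± 0.39, at least 23.9-fold). Ionotropic transmitter receptor genes had 5 of 16 lower and 1 higher (camera adjusted p = 0.0239, adjusted p = 0.199 with an estimated correlation), with the glutamate receptor gene GluRIA (-3.80 ± 0.44) and the GABA receptor gene Rdl (-2.48 ± 0.27) lower. Photoreceptor genes had medians of 9.8 in ELAV and 6.41 in large PDF neurons.

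Kenyon cell and learning genes had 6 of 12 lower and 1 higher (7 and 2 adjusted over the list alone, camera adjusted p = 0.0214, adjusted p = 0.246 with an estimated correlation), with mub (-5.98 ± 0.53), dac (-4.81 ± 0.57) and fru (-3.58 ± 0.57) lower. Of 27 transmitter and peptide receptor genes 10 were lower and 5 higher (14 and 5 adjusted over the list alone, camera adjusted p = 0.0663), including the muscarinic receptor gene mAChR-B (-7.34 ± 0.23, at least 26-fold, adjusted p = 1.62e-13), the leucokinin receptor gene Lkr (-5.07 ± 0.51, at least 11.9-fold) and the serotonin receptor gene 5-HT1A (-4.89 ± 0.48). Of 16 neuronal identity factors 8 were lower and 3 higher (camera adjusted p = 0.0702), with pros (-4.43 ± 0.64) lower. Lower as well were jdp (-5.91 ± 0.49), the phenoloxidase gene PPO2 (-5.14 ± 0.37), CG12239 (-9.30 ± 0.79), CG15537 (-8.33 ± 0.40, at least 53-fold), the phosphodiesterase gene Pde1c (-3.64 ± 0.34) and the teneurin gene Ten-m (-4.06 ± 0.43). The potassium channel gene Irk1 (3 ± 0.49), the transporter gene MFS3 (3.58 ± 0.30) and the adenylyl cyclase genes Ac13E (2.75 ± 0.19) and Ac76E (2.11 ± 0.44) were higher. So were the axon guidance gene beat-Ia (2.42 ± 0.38), the synaptotagmin gene Sytbeta (2.92 ± 0.30) and the sterol carrier gene Npc2a (2.25 ± 0.26). The diacylglycerol kinase gene rdgA was lower (-4.59), with 1 of 2 other probe sets opposite in sign. Haemocyte genes had medians of 7.61 in ELAV and 6.47 in large PDF neurons. Gene by gene the direction was not the same, with a median difference of 0.48 and a mean of -0.24 over the 6 measured.

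Of 30 cytosolic ribosomal protein genes 12 were higher and 0 lower (17 adjusted over the list alone, camera adjusted p = 5.72e-06, adjusted p = 0.246 with an estimated correlation), for example RpLP1 (1.01 ± 0.18). Of 61 respiratory chain and ATP synthase genes 21 were lower and 0 higher (24 adjusted over the list alone, camera adjusted p = 1.46e-05, adjusted p = 0.285 with an estimated correlation), for example the complex I genes ND-20 (-1.47 ± 0.36) and ND-B14.7 (-1.21 ± 0.20).

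The other lists were not called in large PDF neurons against ELAV (camera adjusted p from 0.0559 to 0.941). Photoreceptor genes had 5 of 9 lower and 0 higher, and glial genes 1 of 10 higher and 0 lower. Fat body genes had 4 of 8 higher and 0 lower, haemocyte genes 1 of 6 lower and 0 higher, and muscle genes 1 of 8 higher and 1 lower. Lysosome and autophagy genes had 3 of 18 higher and 0 lower, and ion channel genes 4 of 35 higher and 7 lower. Genes of cAMP and calcium signalling had 3 of 20 higher and 6 lower, peptide processing genes 3 of 13 higher and 2 lower, and synaptic vesicle genes 2 of 25 higher and 4 lower. Sex-biased genes had 1 of 8 higher and 1 lower, chaperone genes 1 of 11 higher and 0 lower, and activity-regulated genes 2 of 12 higher and 2 lower. Immune genes had 1 of 7 lower and 0 higher, nuclear receptors 2 of 13 higher and 1 lower, and neurite growth and adhesion genes 4 of 26 higher and 4 lower.

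Small PDF neurons also carried Pdf and clock transcripts above general neurons, and 11 of 15 transmitter synthesis and transport genes were lower in them. Activity-regulated and stress-kinase genes were higher, 7 of 12. In all 2295 probe sets were called, 1128 higher and 1167 lower (1869 genes), and 1910 of these differed at least 2-fold. The largest rises were Pdf (12.23 ± 0.33), cry (8.46 ± 0.53), CG15784 (8.22), Clk (8.03 ± 0.49, at least 50.8-fold) and the citrate transporter gene Indy (7.77 ± 1.29). Next came CG17777 (7.10), vri (6.57 ± 0.45), bnb (6.30 ± 0.93), tim (6.12 ± 0.35) and the bHLH repressor gene hry (6.05 ± 1.22, adjusted p = 0.00113). Photoreceptor genes had medians of 9.8 in ELAV and 7.8 in small PDF neurons.

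Among the 8 core clock genes 7 were higher and 0 lower (camera adjusted p = 1.98e-10). Further ones were per (4.47 ± 0.41), cwo (4.15 ± 0.29) and Pdp1 (2.09 ± 0.32, adjusted p = 8.76e-05), and cyc stood at 0.15 (adjusted p = 0.762). Of the 11 genes known to cycle in whole heads 7 were higher and 0 lower (camera adjusted p = 8.12e-07). Also higher were Hr51 (5.20 ± 0.71), Fer2 (4.68 ± 0.41), Irk1 (4.54 ± 0.55), tyf (3.55 ± 0.40), ctrip (2.30 ± 0.28), MFS3 (3.72 ± 0.34), the eye determination gene toy (4.07 ± 0.33) and the matrix protease gene Mmp2 (3.83 ± 0.47). Activity-regulated and stress-kinase genes had 7 of 12 higher and 0 lower (camera adjusted p = 2.69e-05). Among them were Gadd45 (4.06 ± 0.43, adjusted p = 1.2e-06), the JNK phosphatase gene puc (3.41 ± 0.66, adjusted p = 0.000745), the zinc finger gene cbt (3.24 ± 0.35) and the nuclear receptor gene Hr38 (2.36 ± 0.69, adjusted p = 0.0156). Hr38 lost its call in 2 of 10 fits without 1 array (adjusted p up to 0.109, without small ZT12 replicate 2).

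Neuropeptide genes had 10 of 22 lower and 1 higher (12 and 1 adjusted over the list alone, camera adjusted p = 9.53e-06). The largest falls were Ms (-11.72 ± 0.68), Mip (-10.55 ± 0.57, at least 467-fold), FMRFa (-10.32 ± 0.48, at least 258-fold), ITP (-10.26 ± 1.01) and CCHa2 (-8.44 ± 0.44). Transmitter synthesis and transport genes had 11 of 15 lower and 0 higher (camera adjusted p = 4.01e-08). They include Gad1 (-9.87 ± 0.86), Vmat (-9.26 ± 0.40), ple (-5.87 ± 0.44, at least 23.9-fold), the serotonin transporter gene SerT (-5.02 ± 1.05, adjusted p = 0.00149) and the dopamine transporter gene DAT (-4.56 ± 0.46). The insulin-binding protein gene ImpL2 (-9.68 ± 0.65, at least 203-fold), mAChR-B (-7.28 ± 0.26, at least 26-fold), jdp (-7.20 ± 0.54), PPO2 (-5.04 ± 0.41), Pde1c (-5.08 ± 0.38), pdm3 (-4.35 ± 0.64), the dopamine receptor gene Dop2R (-4.23 ± 0.76) and dac (-4.03 ± 0.64) were lower too. Haemocyte genes had medians of 7.61 in ELAV and 6.12 in small PDF neurons.

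Of 61 respiratory chain and ATP synthase genes 38 were lower and 0 higher (46 and 1 adjusted over the list alone, camera adjusted p = 3.28e-10, adjusted p = 0.152 with an estimated correlation), for example ND-18 (-1.93 ± 0.29, adjusted p = 6.79e-05) and ND-B14.7 (-1.63 ± 0.23). Synaptic vesicle and active zone genes had 7 of 25 lower and 2 higher (9 and 2 adjusted over the list alone, camera adjusted p = 0.0178, adjusted p = 0.246 with an estimated correlation), with the SNARE gene Snap25 (-1.81 ± 0.30) lower. Identity factors had 8 of 16 lower and 1 higher (camera adjusted p = 0.0166, adjusted p = 0.0999 with an estimated correlation). Kenyon cell and learning genes had 6 of 12 lower and 1 higher (camera adjusted p = 0.00704, adjusted p = 0.211 with an estimated correlation). Ionotropic receptor genes had 6 of 16 lower and 1 higher (camera adjusted p = 0.0478, adjusted p = 0.195 with an estimated correlation). Ribosomal protein genes had 4 of 30 higher and 0 lower (camera adjusted p = 0.0328, adjusted p = 0.544 with an estimated correlation). Glial genes had 4 of 10 higher and 0 lower (camera adjusted p = 0.112).

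Large and small PDF neurons shared 449 probe sets higher and 619 lower than ELAV, where independent calls would give 134 and 146, and 48 went opposite ways. Simulated groups without differences shared 0 calls. Such groups give almost no calls to share, so this count is no measure of the overlap to be expected. The log2 differences correlated at 0.709, against 0.449 in such simulations, where the shared ELAV arrays alone tie them together. With separate ELAV arrays for each kind, split in 18 ways, 205 to 244 were higher and 356 to 396 lower in both, and the correlation was 0.592 to 0.649.

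**Figure D2:**
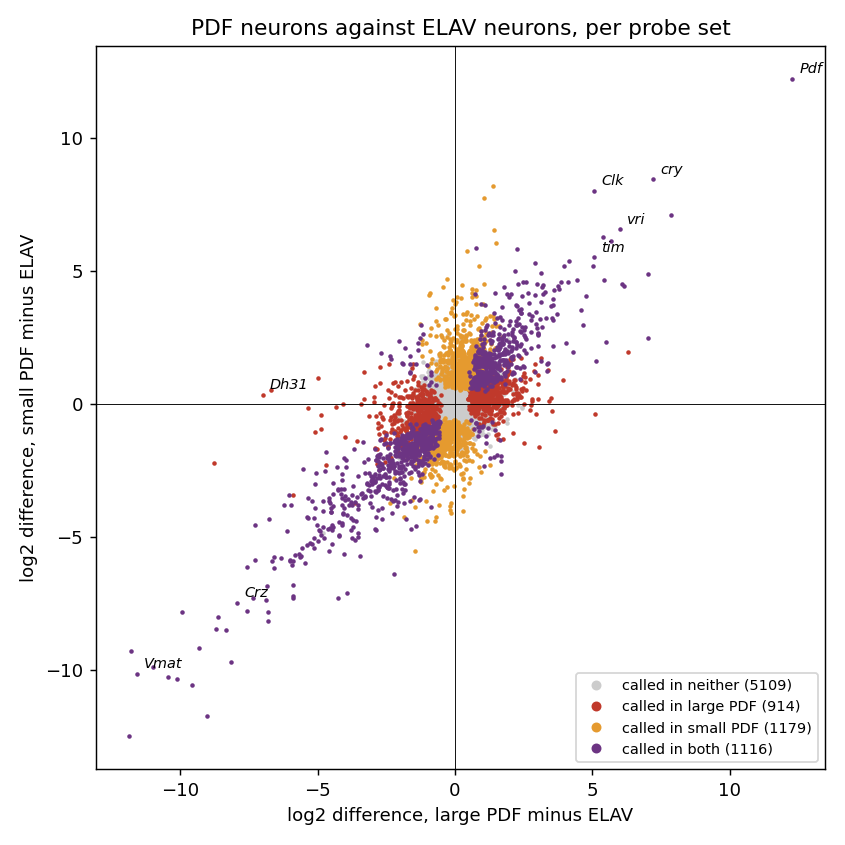
Log2 difference from ELAV neurons in large (horizontal) and small (vertical) PDF neurons for each tested probe set. Colours give the kinds in which the probe set was called.

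**Figure D3:**
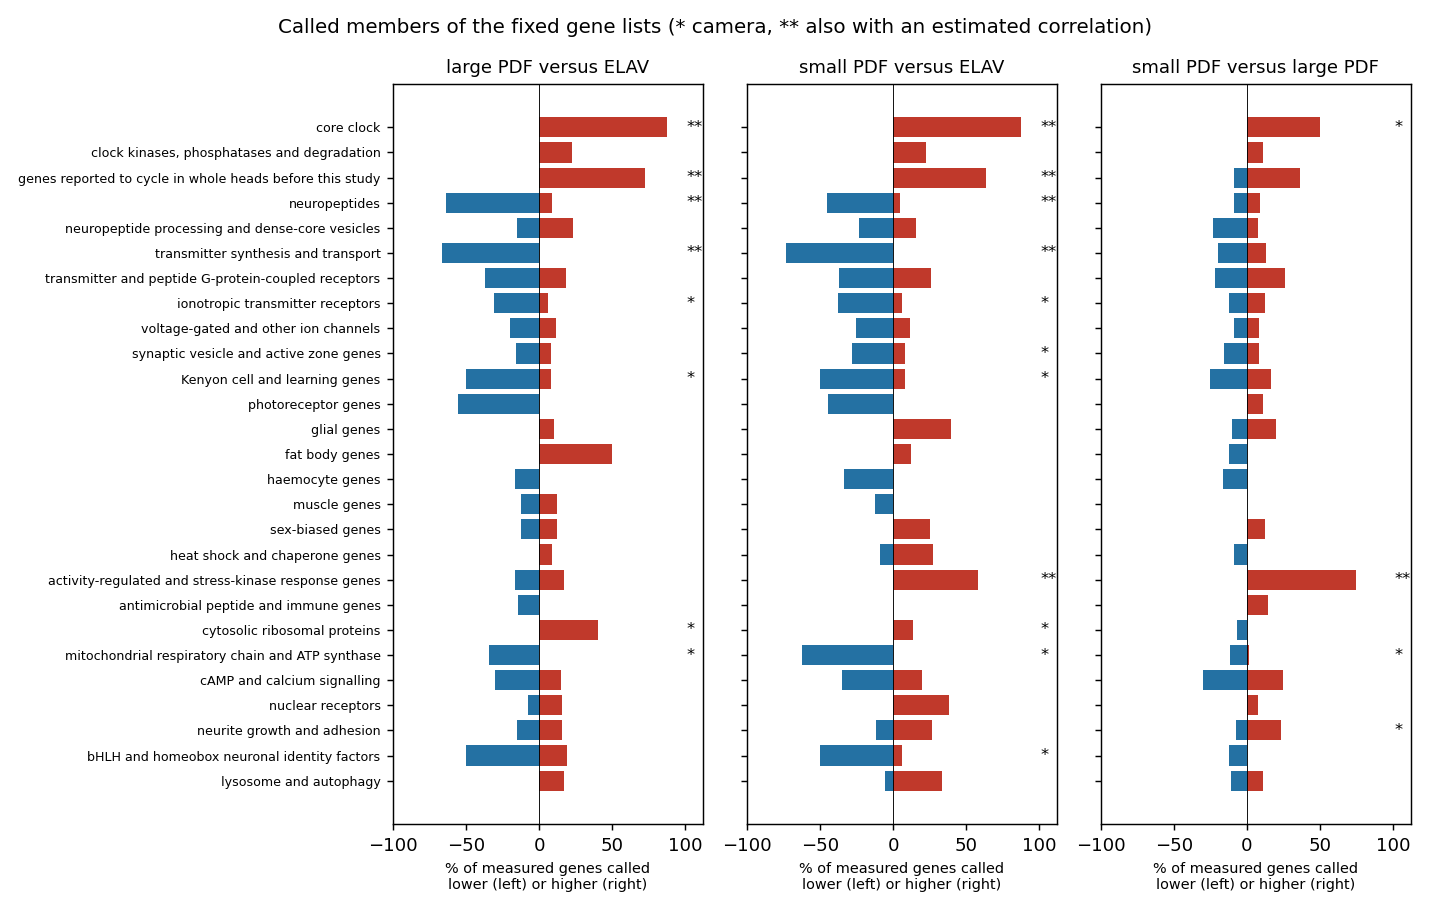
Share of each list's measured genes called lower (left) or higher (right) in the comparisons between kinds of neuron. An asterisk marks lists called by camera and a double asterisk those also called with an estimated correlation.

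Small PDF neurons carried more of Dh31 and sNPF, both neuropeptide genes, of Arc1 and of 9 of 12 activity-regulated genes. As a list neuropeptide genes had 2 of 22 higher and 2 lower (camera adjusted p = 0.925). Transmitter and peptide receptor genes went both ways, with 7 of 27 higher and 6 lower in small PDF neurons (camera adjusted p = 0.299). Between the kinds 1423 of 8318 probe sets were called, 760 higher in small and 663 lower (1187 genes). With only these groups in the fit 802 were called. Higher in small PDF neurons were Dh31 (7.36 ± 0.89, adjusted p = 2.33e-05), the capsid-forming gene Arc1 (7.22 ± 0.88), CG15784 (6.84), Indy (6.71 ± 1.29) and sNPF (6.56 ± 0.84). Higher too were the calcium-binding protein gene Scp2 (5.98 ± 0.73), CG42342 (5.43), Marf1 (4.87 ± 0.24, at least 6.51-fold, adjusted p = 7.55e-10), the kinase gene meng (4.59 ± 0.43) and hry (4.56 ± 1.22, adjusted p = 0.015). The gene hry lost its call in 1 of 10 fits without 1 array (adjusted p up to 0.0507, without small ZT0 replicate 2). Receptor and signalling genes that were higher include 5-HT1A (4.48 ± 0.53), the GABA receptor gene GABA-B-R3 (3.89 ± 0.70), the kinase gene Pka-C3 (3.73 ± 0.62), Mmp2 (3.79 ± 0.47), and the adhesion genes Ten-m (4.07 ± 0.48), Con (3.54 ± 0.49) and beat-Ic (3.52 ± 0.47).

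Activity-regulated and stress-kinase genes had 9 of 12 higher and 0 lower in small PDF neurons (camera adjusted p = 7.27e-05). They include Hr38 (4.41 ± 0.69, adjusted p = 0.000263), Gadd45 (3.29 ± 0.43), puc (3.10 ± 0.66) and the ERK phosphatase gene Mkp3 (2.21 ± 0.39). Core clock genes had 4 of 8 higher and 0 lower (camera adjusted p = 0.00843, adjusted p = 0.0555 with an estimated correlation). These were Clk (2.96 ± 0.49, adjusted p = 0.000419), per (1.28 ± 0.41, adjusted p = 0.0389), Pdp1 (1.21 ± 0.32, adjusted p = 0.0135) and cwo (0.93 ± 0.29, adjusted p = 0.0341). Of these per lost its call in 7 of 10 fits without 1 array (adjusted p up to 0.174, without small ZT12 replicate 1), Pdp1 in 2 of 10 fits without 1 array (adjusted p up to 0.0919, without small ZT12 replicate 2) and cwo in 7 of 10 fits without 1 array (adjusted p up to 0.14, without small ZT0 replicate 1). Not called were tim (0.45), vri (0.58), cry (1.24), cyc (0.42) and Pdf (-0.04), which lay at the top of the range in both kinds. Neurite growth and adhesion genes had 6 of 26 higher and 2 lower (camera adjusted p = 0.0412, adjusted p = 0.0754 with an estimated correlation). Photoreceptor genes had medians of 7.8 in small and 6.41 in large PDF neurons.

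Lower in small, and so higher in large, PDF neurons were CG10126 (-5.49), the piRNA gene mael (-4.65 ± 0.52, at least 7.83-fold), lov (-4.64 ± 0.61), Cpr60D (-4.55 ± 0.39, adjusted p = 6.19e-07) and Tsp42Eo (-4.35 ± 0.87). These were followed by CG3191 (-4.31), CAP (-4.14 ± 0.34, at least 8.22-fold), the sorbitol dehydrogenase gene Sodh2 (-4.04 ± 0.76), the innexin gene Inx7 (-3.97 ± 0.55), the Toll receptor gene 18w (-3.94 ± 0.52) and the peroxidasin gene Pxn (-3.56 ± 0.52). Signalling genes that were lower include the phosphodiesterase gene Pde11 (-3.55 ± 0.65), the SIFamide receptor gene SIFaR (-3.49 ± 0.47) and the octopamine receptor gene Octbeta1R (-3.31 ± 0.47). Ac76E (-3.19 ± 0.49), DAT (-3.13 ± 0.46) and the LIM homeobox gene Lim1 (-3.41 ± 0.52) were lower as well. Respiratory chain genes had 7 of 61 lower and 1 higher (5 and 0 adjusted over the list alone, camera adjusted p = 0.00447, adjusted p = 0.771 with an estimated correlation), with ND-B17 (-1.13 ± 0.24) lower. Fat body genes had medians of 6.21 in small and 7.37 in large PDF neurons.

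Within large PDF neurons the clock's feedback arms moved in opposite directions between ZT0 and ZT12. The repressor genes per and vri rose to ZT12 and Clk, which vri represses, fell. The potassium channel gene Irk1 rose with vri, and the phosphodiesterase gene Pde11 and chinmo fell with Clk. The fit called 182 of 8318 probe sets, 82 higher and 100 lower at ZT12 (161 genes), and 116 without ZT0 replicate 3. With only these groups in limma's fit 0 were called (936 with an unadjusted p under 0.05). Higher at ZT12 were vri (6.29 ± 0.56, adjusted p = 1.71e-05), Irk1 (5.53 ± 0.69, adjusted p = 0.00039), the DNA fragmentation factor gene Drep3 (5.40 ± 0.64), the bHLH gene Sidpn (5.11 ± 0.62), CG14086 (4.92) and CG7272 (4.62). So were Pura (4.17 ± 0.62), the amino acid transporter gene JhI-21 (4.01 ± 0.63), Pgant9 (3.94 ± 0.67), per (3.66 ± 0.52, adjusted p = 0.00155) and the tyrosine decarboxylase gene Tdc2 (3.63 ± 0.52, adjusted p = 0.00155). Further rises were beat-Ic (3.08 ± 0.60, at least 4.85-fold), MFS3 (2.89 ± 0.42), cbt (2.61 ± 0.44, adjusted p = 0.00406), the kinase subunit gene Pka-R1 (1.90 ± 0.31, adjusted p = 0.00298) and ctrip (1.73 ± 0.36, adjusted p = 0.0145). The other probe set of ctrip was opposite in sign, and ctrip lost its call in 1 of 6 fits without 1 array (adjusted p up to 0.0543, without large ZT0 replicate 3).

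Lower at ZT12 were CG11791 (-4.78), which lost its call in 3 of 6 fits without 1 array (adjusted p up to 0.0927, without large ZT12 replicate 3), CG4168 (-4.58) and Pde11 (-4.46 ± 0.82, adjusted p = 0.00717). Also lower were the dopamine receptor gene Dop1R1 (-4.14 ± 0.85, adjusted p = 0.0145), Clk (-3.99 ± 0.62, adjusted p = 0.00213), tinc (-3.59 ± 0.73), chinmo (-3.48 ± 0.54, adjusted p = 0.00213), which encodes a zinc finger factor, the chloride channel gene ClC-a (-2.44 ± 0.47, at least 1.46-fold) and the CCHamide receptor gene CCHa1-R (-1.98 ± 0.36, at least 1.17-fold). Dop1R1 lost its call in 2 of 6 fits without 1 array (adjusted p up to 0.0509, without large ZT0 replicate 3). Pdp1 (1.71 ± 0.40, adjusted p = 0.0311) was higher and lost its call in 5 of 6 fits without 1 array (adjusted p up to 0.11, without large ZT0 replicate 1). Not called were tim (1.22, adjusted p = 0.152), cyc (0.74), cwo (0.79), cry (0.08) and Pdf (-0.12). Core clock genes had 3 of 8 higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.000841). Genes known to cycle in whole heads had 3 of 11 higher and 1 lower (camera adjusted p = 0.0257, adjusted p = 0.117 with an estimated correlation). Clock kinase and degradation genes had 1 of 9 higher (3 adjusted over the list alone, camera adjusted p = 0.0253, adjusted p = 0.117 with an estimated correlation). Respiratory chain genes had 1 of 61 lower and 0 higher (12 adjusted over the list alone, camera adjusted p = 5.96e-09, adjusted p = 0.275 with an estimated correlation). Synaptic vesicle genes had 0 of 25 called (camera adjusted p = 0.018, adjusted p = 0.328 with an estimated correlation).

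In small PDF neurons vri rose and Clk fell to ZT12 as well, and the largest changes include a rise of the Dh31 receptor gene and a fall of chinmo. Here 282 of 8318 probe sets were called, 114 higher and 168 lower at ZT12 (235 genes). Leaving out 1 array gave 156 (ZT12 replicate 1), 166 (ZT0 replicate 1) and 133 (ZT0 replicate 2), and with only these groups in limma's fit 0 were called (877 with an unadjusted p under 0.05). Higher at ZT12 were CG31675 (7.23 ± 0.39, adjusted p = 5e-09), Pura (6.83 ± 0.76, adjusted p = 3.03e-05), vri (6.41 ± 0.69, adjusted p = 2.5e-05), CG43658 (6.15) and Vmat (5.88 ± 0.62). Further rises were the Dh31 receptor gene Dh31-R (5.22 ± 0.58, adjusted p = 3.03e-05), Irk1 (5.01 ± 0.85, adjusted p = 0.00201), the Notch target gene E(spl)m6-BFM (5 ± 0.29, at least 8.84-fold, adjusted p = 9.57e-09), ctrip (3.28 ± 0.43, adjusted p = 0.000208) and the peptide gene Dh44 (4.90 ± 0.99, adjusted p = 0.00814). Dh44 lost its call in 2 of 4 fits without 1 array (adjusted p up to 0.153, without small ZT0 replicate 2). tim (2.20 ± 0.54, adjusted p = 0.0296) was higher and lost its call in 4 of 4 fits without 1 array (adjusted p up to 0.168, without small ZT0 replicate 2). Not called were per (0.96), Pdp1 (1.34), cwo (0.94), cyc (-0.25), cry (-1.46) and Pdf (0.01).

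Lower at ZT12 were chinmo (-7.82 ± 0.66, at least 159-fold, adjusted p = 1.47e-06), CCHa1-R (-5.54 ± 0.44, at least 10.2-fold, adjusted p = 5.53e-07), CG13950 (-5.51) and Hr38 (-5.50 ± 1.07, adjusted p = 0.00619). Also lower were CG34325 (-5.20), the kinase gene Dyrk2 (-5.05 ± 0.72, adjusted p = 0.000391), Rcd2 (-4.56 ± 0.46, at least 6.91-fold) and the protease gene Fur2 (-4.38 ± 0.66). Hr38 lost its call in 2 of 4 fits without 1 array (adjusted p up to 0.106, without small ZT12 replicate 1). Clk (-3.68 ± 0.76, adjusted p = 0.00913) was lower and lost its call in 3 of 4 fits without 1 array (adjusted p up to 0.0777, without small ZT0 replicate 1). Transmitter and peptide receptor genes had 5 of 27 higher and 2 lower (6 and 2 adjusted over the list alone, camera adjusted p = 0.0452, adjusted p = 0.367 with an estimated correlation). Respiratory chain genes had 8 of 61 lower and 0 higher (13 adjusted over the list alone, camera adjusted p = 1.63e-14, adjusted p = 0.367 with an estimated correlation). Core clock genes had 2 of 8 higher and 1 lower (3 and 1 adjusted over the list alone, camera adjusted p = 0.133). The kinds shared 18 probe sets higher and 24 lower at ZT12, where independent calls would give 1.1 and 2, and 1 went opposite ways. Shared rises include vri, Irk1, Pura and the monocarboxylate transporter gene Mct1 (2.44 in large and 3.2 in small). Shared falls include chinmo, CCHa1-R and all 3 probe sets of the glycerol phosphate dehydrogenase gene Gpdh1 (for 1 of them -3.34 in large and -4.23 in small).

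In ELAV neurons 2 of 8318 probe sets were called between ZT12 and ZT0. eya (1.94 ± 0.27, at least 1.18-fold, adjusted p = 0.00873), an eye development gene, was higher at ZT12 and the transcription factor gene kn (-2.76 ± 0.42, at least 3.01-fold, adjusted p = 0.0172) lower. After requantiling eya had an adjusted p of 0.092, and kn lost its call in 2 of 6 fits without 1 array (adjusted p up to 0.177, without ELAV ZT0 replicate 2). Counts without 1 array ran from 1 (without ZT0 replicate 2) to 7 (without ZT12 replicate 1 or 2), and with only these groups in limma's fit 0 were called (386 with an unadjusted p under 0.05). vri stood at 2.59 (adjusted p = 0.277), per at 0.37, tim at -0.47, Clk at -0.22, cyc at -0.16, Pdp1 at -0.01, cwo at -0.13, cry at 0.07 and Pdf at 0.80. Respiratory chain genes had 0 of 61 called (camera adjusted p = 0.00441, adjusted p = 0.702 with an estimated correlation).

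In per01 large PDF neurons 1 of 8318 probe sets was called between ZT12 and ZT0, CG4830 (-2.73 ± 0.31, at least 1.6-fold, adjusted p = 0.000567), and 301 had an unadjusted p under 0.05. Without ZT0 replicate 1 the count was 3, and with only these groups in limma's fit it was 0 (546 unadjusted). vri stood at 13.2 at ZT0 and 13.3 at ZT12 (0.08), Clk at 1.28 and per at 0.64, each with an adjusted p of 1. Not called either were tim (0.16), cyc (-0.60), Pdp1 (0.37), cwo (0.50), cry (1.14) and Pdf (0.01). Lists called by camera had no called member. These were peptide processing (adjusted p = 0.0468, adjusted p = 0.673 with an estimated correlation), activity-regulated (adjusted p = 0.0468, adjusted p = 0.582 with an estimated correlation), ribosomal protein (adjusted p = 0.0468, adjusted p = 0.738 with an estimated correlation) and respiratory chain genes (adjusted p = 0.0181, adjusted p = 0.738 with an estimated correlation).

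**Figure D4:**
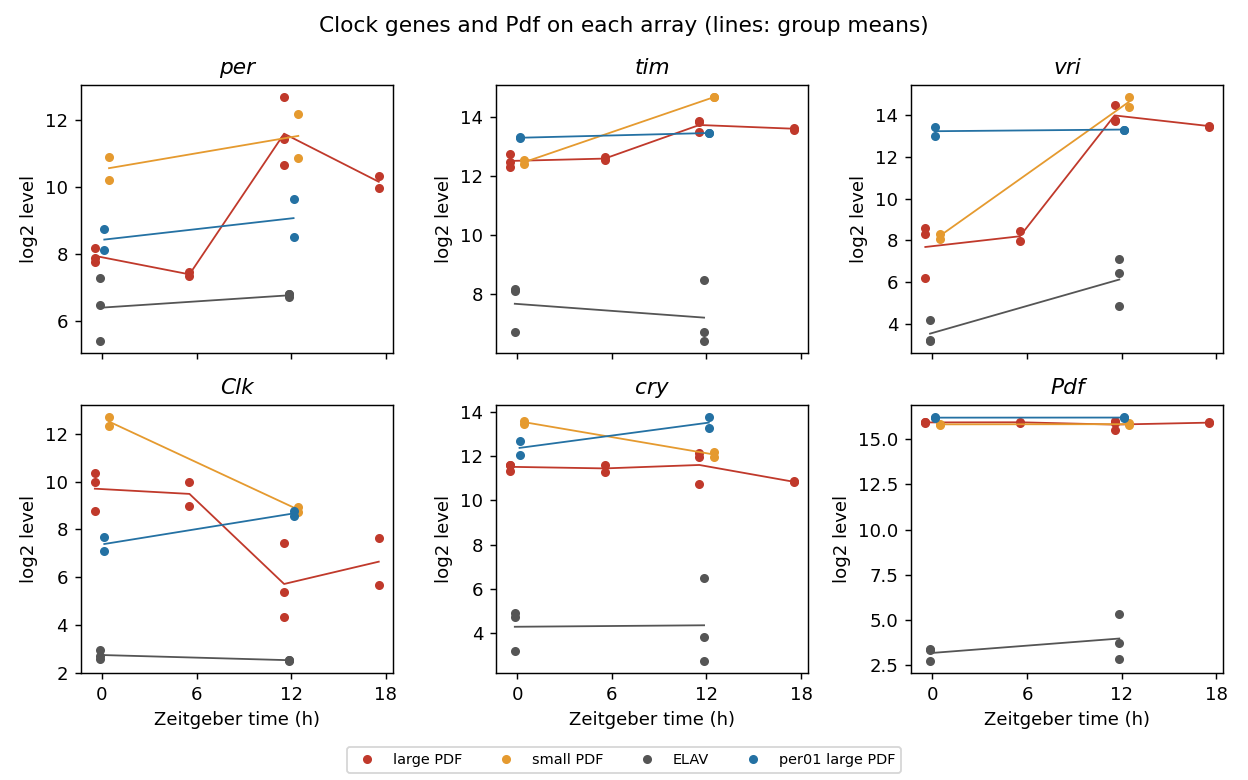
Log2 levels of clock genes and Pdf on each array against zeitgeber time. Lines join group means.

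Of the 182 probe sets called between ZT12 and ZT0 in wild-type large PDF neurons, 100 (54.9%) had the same sign in per01, with 0 called and a median difference of 0.04 in the wild-type direction. The 182 were chosen on the wild-type arrays, where their median is 2.2. For probe sets called on 2 wild-type arrays per time, the median in the wild-type arrays left out was 0.736 to 1.65, and in per01 0.00397 to 0.175. In small PDF neurons 140 (76.9%) had the same sign, with a median of 0.83, and 42 were called the same way. In ELAV neurons 105 (57.7%) had the same sign, with a median of 0.06 and 0 called. Some of the 182 lay at background in the neurons where they were followed, which may hide a change. Clk was at 2.5 to 2.96 on ELAV arrays and Anp at 2.57 to 2.62 on per01 arrays. Such probe sets were not counted. The small medians in per01 and ELAV neurons therefore do not measure how much change was lost.

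**Figure D5:**
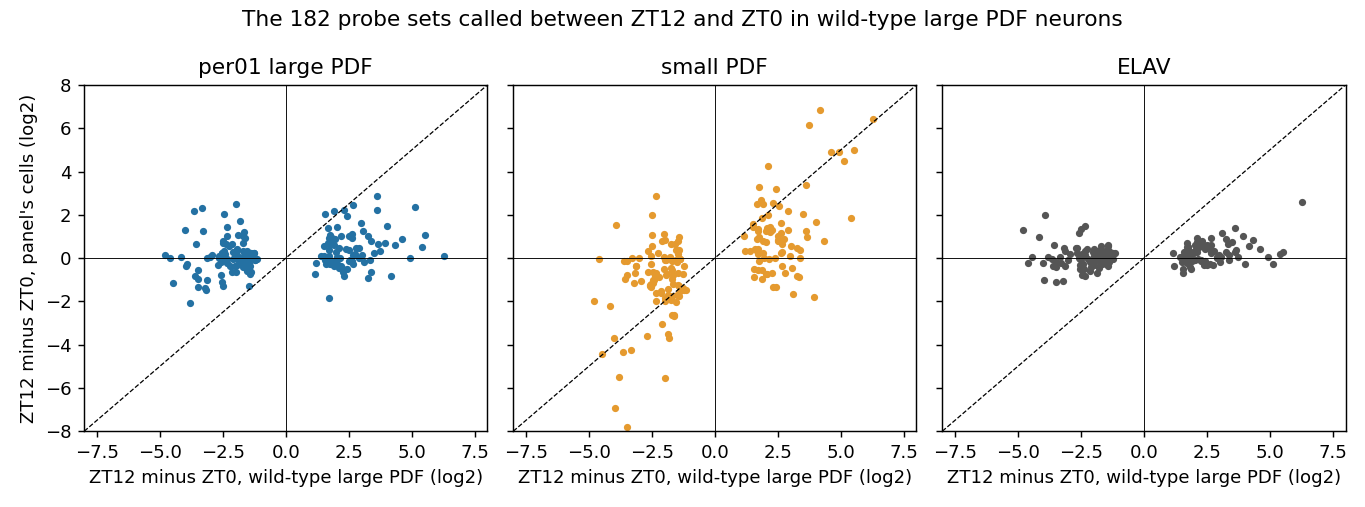
ZT12 minus ZT0 of the 182 probe sets called in wild-type large PDF neurons (horizontal) against the same difference in per01 large PDF, small PDF and ELAV neurons (vertical). The dashed line marks equality.

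Over 4 times in large PDF neurons per and vri peaked at ZT12 and Clk in the first part of the day, and further genes peaked at ZT6 and ZT18. In total 168 of 8318 probe sets changed over time by limma's F test (153 genes), with the highest mean at ZT0 in 50, ZT6 in 25, ZT12 in 68 and ZT18 in 25, and 111 of them were also called between ZT12 and ZT0. Without ZT18 replicate 1 the count was 100, and with only these groups in the fit 26. At ZT0, ZT6, ZT12 and ZT18 vri stood at 7.69, 8.20, 13.98 and 13.46 (adjusted p = 1.4e-05), per at 7.94, 7.39, 11.60 and 10.16 (adjusted p = 0.000926), Clk at 9.70, 9.49, 5.72 and 6.65 (adjusted p = 0.00308) and Pdp1 at 10.44, 9.90, 12.16 and 12.85 (adjusted p = 0.00343). The CLK-interacting protein gene Cipc stood at 9.31, 7.37, 10.03 and 11.30 (adjusted p = 0.00251), chinmo at 10.01, 7.64, 6.53 and 4.57 (adjusted p = 0.000844), Irk1 at 4.53, 4.32, 10.06 and 6.40 (adjusted p = 0.000844), Sidpn at 6.66, 8.61, 11.77 and 8.81 (adjusted p = 0.00116) and Drep3 at 3.64, 3.05, 9.04 and 7.46 (adjusted p = 0.000308).

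Peaks outside ZT0 and ZT12 include Pura at 4.35, 6.13, 8.51 and 9.35 (adjusted p = 0.00116), the arginine kinase gene Argk1 at 12.47, 12.95, 12.14 and 9.78 (adjusted p = 0.000844), the collagen gene Mp at 8.74, 10.92, 9.91 and 7.17 (adjusted p = 0.00741) and the protease gene Jon99Fi at 3.03, 7.50, 3.13 and 5.78 (adjusted p = 0.00564). The 2 arrays per time of Jon99Fi differed widely, with standard deviations of 1.93 at ZT6 and 2.65 at ZT18, so its peak is uncertain. Argk1 differed mainly by its low at ZT18. Mp lost its call in 1 of 10 fits without 1 array (adjusted p up to 0.0501, without large ZT18 replicate 2). Pde11 at 12.68, 11, 8.22 and 11.71 (adjusted p = 0.0251) and Dop1R1 at 9.89, 6, 5.75 and 9.07 (adjusted p = 0.025) had their low at ZT12. Pde11 lost its call in 3 of 10 fits without 1 array (adjusted p up to 0.0849, without large ZT12 replicate 2) and Dop1R1 in 3 of 10 fits without 1 array (adjusted p up to 0.0609, without large ZT0 replicate 3). Not called were tim (12.5, 12.58, 13.72 and 13.59, adjusted p = 0.237), cwo (adjusted p = 0.076), cyc (adjusted p = 0.435), cry (adjusted p = 0.897) and Pdf (adjusted p = 0.999).

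The day and night difference depended on genotype most strongly for the clock gene vri. The interaction was called for 12 of 8318 probe sets, 7 higher and 5 lower. Leaving out 1 array gave 2 (without large PDF ZT0 replicate 2) to 34 (without large PDF ZT0 replicate 1). With only these groups in limma's fit 0 were called (568 with an unadjusted p under 0.05). The per01 difference minus the wild-type one was -6.21 ± 0.89 for vri (adjusted p = 0.00879) and 5.27 ± 0.98 for Clk (adjusted p = 0.0345). Clk lost its call in 8 of 10 fits without 1 array (adjusted p up to 0.189, without per01 ZT12 replicate 1). For genes not called it was -3.01 (per, adjusted p = 0.268), -1.06 (tim), -1.34 (cyc), -1.35 (Pdp1), -0.29 (cwo), 1.06 (cry) and 0.12 (Pdf). Core clock genes had 1 of 8 higher and 1 lower (1 and 2 adjusted over the list alone, camera adjusted p = 0.0192, adjusted p = 0.142 with an estimated correlation). Respiratory chain genes were called by camera (adjusted p = 0.0192, adjusted p = 0.61 with an estimated correlation).

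Against ELAV neurons the large PDF difference between times was greater for single genes that rose at ZT12, among them Irk1 and Sidpn. The mean of Irk1 in ELAV neurons was under log2 5, where background may hide a change. Of 8318 probe sets 8 were called, 5 higher and 3 lower (7 genes), with counts from 1 (without ELAV ZT12 replicate 3) to 45 (without large PDF ZT0 replicate 1). With only these groups in the fit 1 was called. Higher were CG43658 (3.67 ± 0.52), Sidpn (5.38 ± 0.87, adjusted p = 0.0362), Drep3 (5.22 ± 0.91) and Irk1 (5.24 ± 0.98, adjusted p = 0.0474). Sidpn lost its call in 6 of 12 fits without 1 array (adjusted p up to 0.0655, without ELAV ZT12 replicate 3), Drep3 in 7 of 12 fits without 1 array (adjusted p up to 0.086, without ELAV ZT0 replicate 1) and Irk1 in 10 of 12 fits without 1 array (adjusted p up to 0.12, without ELAV ZT0 replicate 2). Not called were vri (3.70, adjusted p = 0.0826), per (3.28, adjusted p = 0.0856), Clk (-3.77, adjusted p = 0.103), tim (1.69), cyc (0.90), Pdp1 (1.72), cwo (0.93), cry (0.02) and Pdf (-0.92). Core clock genes had 0 of 8 called (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00321). Respiratory chain genes were called by camera (adjusted p = 0.00504, adjusted p = 0.542 with an estimated correlation).

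Between the kinds of PDF neuron the size of the time difference differed for single genes such as Vmat, the Notch target gene E(spl)m6-BFM and the CCHamide receptor gene CCHa1-R. Vmat was under log2 5 on all large PDF arrays at ZT0 and ZT12, where background would hide a change. CCHa1-R fell in both kinds (-1.98 in large and -5.54 in small), and its fall in large PDF neurons reached under 5. Of 8318 probe sets 58 were called, 20 higher and 38 lower (53 genes), and with only these groups in the fit 5. The small PDF difference exceeded that of large PDF neurons for Vmat (5.86 ± 0.81, adjusted p = 0.00146), the protease gene Nepl20 (5.21 ± 0.58, adjusted p = 0.00016), E(spl)m6-BFM (4.95 ± 0.38, adjusted p = 7.39e-07) and CG31675 (7.06 ± 0.51). It did so for Dh31-R (4.14 ± 0.75, adjusted p = 0.0123), which lost its call in 1 of 10 fits without 1 array (adjusted p up to 0.0749, without small ZT0 replicate 2). It was lower for CCHa1-R (-3.56 ± 0.56, adjusted p = 0.00418), Rcd2 (-4.12 ± 0.60, adjusted p = 0.00224) and CG34325 (-5.41 ± 0.83), and for chinmo (-4.34 ± 0.86, adjusted p = 0.0215), which lost its call in 3 of 10 fits without 1 array (adjusted p up to 0.094, without small ZT0 replicate 2). Transmitter and peptide receptor genes had 1 of 27 higher and 2 lower (3 and 2 adjusted over the list alone, camera adjusted p = 0.0441, adjusted p = 0.446 with an estimated correlation). For clock genes, none called, it was -2.69 (per, adjusted p = 0.17), 0.98 (tim), 0.31 (Clk), -0.99 (cyc), 0.12 (vri), -0.37 (Pdp1), 0.15 (cwo) and -1.54 (cry), and for Pdf 0.13.

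The transcript of per stood at 9.64, 8.50, 8.75 and 8.11 on the 4 per01 arrays, at 7.77, 7.87 and 8.18 on wild-type ZT0 arrays and at 11.4, 12.7 and 10.7 on wild-type ZT12 arrays. The per01 allele is a point mutation, so its transcript level does not show the genotype. In per01 neurons vri stayed at its high ZT12 level at both times, and Pdp1 was higher, while a muscarinic receptor gene absent from wild-type PDF neurons was on. Per the labels the per01 flies were male and the other flies of both sexes, so sex and genotype are not separable here.

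Of 8318 probe sets 2659 were called between per01 and wild type (2188 genes), 77 higher and 2582 lower. The median difference of all tested probe sets was -0.69. After requantiling the median was 0.01 and 587 were called, 259 higher and 328 lower, and 77 higher and 328 lower were called in both versions. Without per01 ZT12 replicate 1 the count was 1744. Median centring gave 848.

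Higher in per01, with the requantiled difference second, were vri (2.43 ± 0.45, requantiled 2.82), mAChR-B (6.73 ± 0.26, at least 17.1-fold, requantiled 7.19), the cilium and flagellum genes Tektin-C (5.64 ± 0.56, requantiled 6.19) and IFT54 (3.79 ± 0.34, at least 3.93-fold, requantiled 4.52), and CG2444 (4.22). So were firl (3.37 ± 0.71, requantiled 4.16), SKIP (3.31 ± 0.53, requantiled 3.97), Aduk (2.52 ± 0.36, requantiled 3.19), the dopamine receptor gene Dop1R1 (2.51 ± 0.67, requantiled 2.94) and the zinc finger gene sr (2.10 ± 0.48, requantiled 2.87). The mitochondrial carrier gene Bmcp (3.23 ± 0.30, requantiled 3.82) was higher, with its other probe set opposite in sign. Pdp1 (1.21 ± 0.32, requantiled 1.55) was higher and lost its call in 1 of 10 fits without 1 array (adjusted p up to 0.0628, without per01 ZT0 replicate 2). The complex I gene ND-18 (0.96 ± 0.29, requantiled 1.44) lost its call in 2 of 10 fits without 1 array (adjusted p up to 0.109, without per01 ZT12 replicate 1). Not called were per (-1.02, adjusted p = 0.0641), cry (1.38, adjusted p = 0.0546), tim (0.26), Clk (0.32), cyc (-0.47), cwo (-0.56) and Pdf (0.33).

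Lower in per01 in both versions were CG14292 (-6.15, at least 10.3-fold), the andropin gene Anp (-5.65 ± 0.45, at least 9.46-fold, requantiled -5.02), the acyl-CoA synthetase gene pdgy (-5.35 ± 0.60, at least 6.61-fold, requantiled -5.06), and CG13868 (-4.53, at least 12.2-fold). So were lilli (-3.95 ± 0.48, at least 6.08-fold, requantiled -2.77), the transporter gene Orct (-3.69 ± 0.55, at least 2.73-fold, requantiled -2.85), the collagen gene Col4a1 (-3.69 ± 0.81, requantiled -3.18), which was at 10.37 on wild-type ZT0 replicate 2, and the peptide gene Dh44 (-3.37 ± 0.64, at least 1.79-fold, requantiled -2.96). Neuronal genes among them were the adhesion gene Con (-3.12 ± 0.49, requantiled -2.08) and the sodium channel helper gene Teh2 (-2.96 ± 0.34, at least 1.86-fold, requantiled -1.86). The potassium channel gene Shaw (-2.95 ± 0.38, at least 1.91-fold, requantiled -1.89) and Sytbeta (-2.32 ± 0.34, requantiled -1.39) were others. Folds given as at least in this paragraph come from the deposited values and include their median difference of -0.69. They are therefore not lower bounds for the requantiled values. The yolk protein genes, which are expressed in females, stood at -2.90 (Yp1, adjusted p = 0.0178), -2.28 (Yp2, adjusted p = 0.00158) and -1.60 (Yp3, adjusted p = 0.187). Yp1 had an adjusted p of 0.257 and Yp2 of 0.0641 after requantiling, and Yp1 lost its call in 2 of 10 fits without 1 array (adjusted p up to 0.074, without per01 ZT0 replicate 1). Sex-biased genes had 3 of 8 lower and 0 higher (camera adjusted p = 0.642, median difference -1.13), and 0 called in limma's fit after requantiling (camera adjusted p = 0.54, median difference -0.47).

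Core clock genes had 2 of 8 higher and 0 lower (3 and 1 adjusted over the list alone, camera adjusted p = 0.000808), and 3 higher and 0 lower after requantiling (camera adjusted p = 0.0331, adjusted p = 0.197 with an estimated correlation). Respiratory chain genes had 7 of 61 lower and 1 higher (2 and 0 adjusted over the list alone), with camera upward relative to the other genes (adjusted p = 0.000229, adjusted p = 0.773 with an estimated correlation). They had 5 higher and 0 lower after requantiling (camera adjusted p = 0.000343, adjusted p = 0.674 with an estimated correlation). Ion channel genes had 16 of 35 lower and 0 higher, and 6 lower and 3 higher after requantiling. Neuropeptide genes had 8 of 22 lower and synaptic vesicle genes 9 of 25, and 1 each after requantiling. Lysosome genes had 8 of 18 lower and ribosomal protein genes 11 of 30, and 0 after requantiling in limma's fit.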

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

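The patterns weighed in this part were picked after the comparisons had been computed. The criteria for the share of lower calls in per01 and for other neurons in the per01 sort were written after results were seen, and those of the other tests before their values were known.

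Differences between groups in their change over time drew attention to these genes. In the interaction of time and genotype 12 probe sets were called, with a difference of -6.21 for vri, 5.27 for Clk, -3.56 for nej, -2.75 for CG4830, 2.72 for CG18549, 2.85 for Rim2, 4.48 for l(1)G0469, 4.46 for ClC-a, 4.57 for CG8916, -4.92 for CG14086 and -3.39 for CG43658. In the interaction of time with large PDF against ELAV 8 probe sets were called, with 5.22 for Drep3, 5.24 for Irk1, 5.38 for Sidpn, -5.81 for pdgy, -4.51 for CG9743, 4.88 for CG14086 and 3.67 for CG43658. In the interaction of time with small against large PDF 58 probe sets were called. Higher ones include Vmat (5.86), Nepl20 (5.21), E(spl)m6-BFM (4.95), GAPsec (4.60), ko (4.50), Dh31-R (4.14), APC10 (2.71), app (2.27), CG31675 (7.06) and CG8401 (5.89). Lower ones include ome (-6.09), Pgant9 (-5.73), Dyrk2 (-4.57), jeb (-4.57), chinmo (-4.34), Rcd2 (-4.12), hlk (-3.91), Cbp53E (-3.83), CG34325 (-5.41) and CG34342 (-4.94).

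Few day and night differences in per01 large PDF neurons were weighed first, with 1 call against 182 in wild type. Fewer arrays cannot account for it, because subsets of 2 wild-type arrays per time gave at least 83 calls. Over 3443 probe sets at log2 7 or more in both, the slope of per01 on wild-type means was 0.965. This argues against compression of the per01 values at those levels only. Some wild-type time calls reach under 7, such as Irk1 at 4.53 at ZT0 and Clk at 5.72 at ZT12, where the slope tells nothing. Pooled variance may also favour wild-type calls, as the median residual standard deviation was 0.619 in large PDF and 0.401 in per01 neurons. With only the groups of each comparison in limma's fit, 0 were called in wild type and 0 in per01. An unadjusted p under 0.05 was found there for 936 probe sets in wild type and 546 in per01. The numbers of calls, 182 and 1, thus rest on the pooled fit. The separate fits keep only 4 and 2 residual degrees of freedom, so they cannot measure how much the pooling adds. The per01 difference over the wild-type difference had a median of 0.047, which may reflect loss of per function, but the per01 flies were also male and no array separates sex from genotype. Probe sets at background in per01 neurons may also lower that median, which was not tested.

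Lower calls made up 97.1% of calls between per01 and wild type and 55.9% after requantiling. Requantiling sets all arrays to a common distribution, which moves that share toward balance whatever the cause, so the value decides nothing. Separate normalization of the per01 arrays and a real difference in the RNA of these cells cannot be told apart here.

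The receptor gene mAChR-B was at least at 8.76 on the per01 arrays and at most at 2.61 on wild-type PDF arrays, with 9.7 as its mean in ELAV, and it was the only 1 of 9743 probe sets off in wild-type PDF arrays that reached log2 7 on all per01 arrays. Other neurons in the per01 sort may bring further ELAV transcripts. The 4 probe sets at least as high in ELAV and off in wild-type PDF arrays had a median of 2.42 in per01. These were FMRFa, Crz, CG15537 and 1 probe set without a gene symbol. They argue only against neurons that carry these transcripts, so the test cannot exclude other neurons in the sort. A first form of this test, with a stricter ELAV level, left 1 probe set and was replaced after that was seen. Probe sets off in wild-type PDF arrays had a median difference of -0.305, which argues against separate normalization raising them as a set. A median over the set cannot exclude an effect on this 1 probe set. Genetic background or sex may account for the level of mAChR-B, and neither was tested.

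Random splits of the arrays called as many probe sets as the real split in 1 of 100 for large PDF against ELAV (highest other 609), 1 of 100 for small PDF against ELAV (424), 1 of 100 for small against large PDF (476) and 1 of 100 for per01 against wild type (540), the real split being that 1. For ZT12 against ZT0 it was 1 of 10 in large PDF (highest other 4), and 10 splits are too few to tell there. In ELAV it was 8 of 10 (median of the others 2, highest 16), so those 2 calls are no more than other groupings of the same arrays gave. For the interaction of time with large PDF against ELAV it was 10 of 100 (38), so a grouping by chance may account for those 8 calls.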

How the results depend on the processing

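Leaving out the per01 arrays and using 2 arrays per time were chosen after results were seen. Below, time large, small, ELAV and per01 are the ZT12 against ZT0 counts, genotype, kind and PDF kind the interactions of time with genotype, large PDF against ELAV and small against large PDF, and course the 4 times in large PDF. Of the compared counts 184 were the same and 72 moved. Of gene calls 11404 were the same, 1343 weaker, 18 stronger and 6 reversed, and of list calls 152 were the same, 57 weaker and 1 reversed. With no filter on dim probe sets per01 against wild type gave 6603, time ELAV 5, time per01 4, kind 4 and course 334. With the filter at log2 7 limma gave time ELAV 0 (224 unadjusted), time per01 0 (277 unadjusted) and genotype 21. With values under log2 5 raised to 5 per01 against wild type gave 1662, time per01 2, genotype 20, kind 19 and PDF kind 110. With quantile normalization again per01 against wild type gave 587 and time ELAV 1, the share of higher calls moved from 2.9 to 44.1% in per01, from 58.3 to 47.1% in genotype, from 62.5 to 83.3% in kind and from 50 to 0% in time ELAV, and nAChRalpha7 (0.06), nrv2 (0.14) and ND-B12 (0.26) turned in sign in per01 against wild type. With each array centred on its median per01 against wild type gave 848 (442 higher and 406 lower) and kind 4, and amon (0.11), Sxl (0.09) and Droj2 (0.25) turned in sign. With only the groups in the contrast small against large PDF gave 802 (439 higher and 363 lower), PDF kind 5, kind 1 and course 26, and limma gave time large 0 (936 unadjusted), time small 0 (877), time ELAV 0 (386), time per01 0 (546) and genotype 0 (568). With trend and robust eBayes time large gave 288, limma's time ELAV 0 (330 unadjusted), kind 30 and course 277. With array weights time per01 gave 2, genotype 23 and course 275. With the replicate block time large gave 118, time ELAV 1, genotype 2, kind 2, PDF kind 30 and course 70, though residuals of arrays with the same number correlated only at -0.1 to 0.14. Without the per01 arrays time ELAV gave 1 and kind 1. With 2 arrays per time time large gave a median of 114. Leaving out 1 array gave 1696 to 2057 for large PDF against ELAV, 1859 to 2231 for small PDF against ELAV, 1000 to 1538 for small against large PDF, 1744 to 2795 for per01 against wild type, 116 to 221 for time large, 133 to 254 for time small, 1 to 7 for time ELAV, 1 to 3 for time per01, 2 to 34 for genotype, 1 to 45 for kind, 42 to 76 for PDF kind and 100 to 187 for course. Of 297 list tests 42 were called by camera, 13 with an estimated correlation and 87 by fry, and the respiratory chain list in per01 against wild type turned in direction with fry (-0.09).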

Other observations

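The pattern in this part was picked, and its tests with matched spread, with small PDF neurons and with lower probe sets were chosen, after results were seen.

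Time calls in large PDF neurons were compared between probe sets higher than in ELAV neurons and all others, the lower ones included. Of the 991 probe sets higher in large PDF than in ELAV neurons 57 (5.75%) changed over the time course, against 1.51% of the 7327 others, 3.23 times the number expected at matched level, and because the same arrays enter both calls this ratio alone cannot tell why. Matching on residual spread as well left a ratio of 2.75, and taking probe sets higher in small PDF neurons, whose arrays enter the time course only through the pooled variance, left 2.33, so neither shared spread nor shared arrays is likely the whole explanation. The ratio of higher to lower probe sets was 1.09 (permutation p = 0.08), with 40 of 1039 lower ones (3.85%) called, a ratio of 1.94. Time calls thus went with a difference from ELAV of either sign. Whether PDF enrichment adds to this is not settled, because the higher and lower probe sets were not clearly separated.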
